A study of Homo sapiens with 6 samples.

How the data were processed

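Poly(A) RNA from human PC9 lung cancer cells was sequenced as 6 libraries, 3 control and 3 with PSAT1 silenced by short hairpin RNA. Per the labels, cells grew in medium with 10% serum, were starved of serum for 24 hours at 70% confluency, and libraries were made with a stranded mRNA kit after poly(A) enrichment. The authors deposited 1 table of raw counts per Ensembl gene, with 44452 genes and 1 column per library. Per the submitters' processing notes, FastQC 0.10.1, STAR 2.6, HTSeq 0.10.0 and the hg38 assembly were used; the annotation release, the strand setting and other options are not given in the sources used here. The table holds whole numbers that were not normalized, and no rows of unassigned reads. It holds no mitochondrially encoded genes, so the share of mitochondrial reads was not assessed and 1 of 27 fixed gene lists could not be tested.

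Gene names, positions, exon lengths and GC content came from GENCODE 29 on GRCh38, the same assembly, which matched 44392 of 44452 identifiers; 60 had no name. GC content and length were known for 99.95% of tested genes. Library totals were 15594153 to 23291858 counts. Counts were summed over reads without molecular identifiers, so counting intervals and floors cover counting error only.

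Analyses ran in R 4.3.3. Genes passing edgeR's filterByExpr, 14515 of them, were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, two-sided, robust off, design with group only). Benjamini-Hochberg adjusted p under 0.05 was the threshold, and a fold change of at least 2 was a further count. Printed SEs are the log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled, and log2 CPM used a prior count of 2. On counts simulated for 14515 genes from the real means, dispersions and library sizes, with 200 changed genes, the test recovered 80.4% of 2-fold and 97.4% of 4-fold changes in the silenced against control comparison over 5 runs, and 5.63% of calls were false. In the same simulations the list test found a list of 30 genes changed 1.5-fold in 5 of 5 runs, and the position scan found a block of 50 lower genes in 5 of 5. Genes were drawn independently and all 30 list members were shifted, so lists with correlated members or smaller shifts were not covered. The block lay at the start of chromosome 18 with a shift close to the observed one there, so detection of smaller shifts was not covered either. The recovery runs held no GC-content trend and far fewer changed genes than the 2605 called, so recovery in the real comparison may differ.

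The gene lists were fixed before the data were examined. The main list test was camera with an inter-gene correlation of 0.01, adjusted over 26 lists; camera with an estimated correlation and fry, which does not compare a list with other genes, stood beside it. PSAT1 was left out of the list tests as the target. The 6 lists that passed did not pass with an estimated correlation. Named genes followed a rule also fixed beforehand: PSAT1; the 10 largest rises and 10 largest falls with adjusted p under 0.05, a mean of at least 2 CPM over the 6 libraries, a symbol that is not a clone name and groups that do not overlap; the 3 smallest p-values per direction under the same conditions; and up to 4 passing members per list by size, or 2 by p where none passed. Other genes were named after their values were seen: further members of lists, the chromosome 18 and chromosome 7 genes, EGFR, PHGDH and PSPH, and NDC80 of the G2/M list.

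Replicates were compared with a chi-square statistic over genes with at least 10 counts in a pair. It was 2.55 to 3.64 per degree of freedom among silenced libraries and 7.71 to 38.4 among controls, so no pair agreed within sampling noise and all 6 were kept as separate libraries.

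Position was examined with a running median of log2 fold changes over 31 neighbouring tested genes, against 1000 permutations of gene order. Alternatives were the replicate number as a block, other size factors, no TMM factors, other count filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), a robust fit, an adjusted p of 0.01, a test against a fold change of 1.5, each library left out, local-regression offsets for GC content and gene length (span 0.3) with and without the block, and other list tests. Leaving out the chromosome 18 short-arm genes, and all genes of shifted regions, was added after the data were seen. Figures were drawn with matplotlib 3.10.9.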

Results

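PC9 is an established human lung adenocarcinoma line with an activating EGFR mutation. PSAT1 encodes phosphoserine aminotransferase, an enzyme of the pathway that makes serine from a glycolytic intermediate. The series compared PC9 cells with PSAT1 stably silenced by short hairpin RNA with PC9 control cells. Poly(A) RNA was sequenced from 3 control and 3 silenced libraries, all from cells starved of serum for 24 hours at 70% confluency. The series title names EGF stimulation, and no sample label names added EGF. Library totals were 17917841, 20924402 and 16261977 counts in the controls and 18017615, 15594153 and 23291858 counts in the silenced cells. The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these libraries, which may be technical. The number of hairpin sequences and of silenced populations is also not given, so the comparison is between these silenced cells and these controls, and effects of a hairpin or population are not separated from those of PSAT1 loss.

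The first principal component of log2 CPM (counts scaled to library size) held 54.5% of the variance and separated the groups, at -31.6 to -23.3 for controls and 24.7 to 27.5 for silenced libraries. The second component held 26.6% and set control replicate 1, at 33.8, apart from control replicates 2 and 3, at -27.4 and -11.9. With genes split into 10 equal classes by GC content, the median gene of the highest class in control replicate 1 lay at -0.59 on the log2 scale relative to the mean of the 6 libraries, against 0.13 in the lowest class. Control replicate 2 leaned the other way, with 0.37 in the highest class and -0.12 in the lowest.

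**Figure D1:**
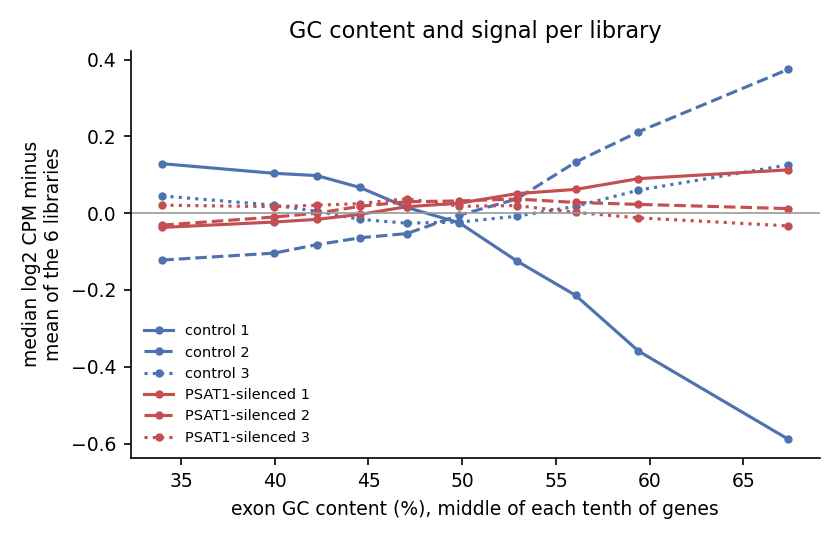
Median log2 CPM minus the mean of the 6 libraries (vertical axis) for genes in 10 equal classes of exon GC content (horizontal axis, %), with 1 line per library, blue for control and red for PSAT1-silenced. Control replicate 1 lies at -0.59 in the highest class, where the silenced libraries lie between -0.03 and 0.11.

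PSAT1 itself (ENSG00000135069, chromosome 9, 78297143 to 78330093, GRCh38) was depleted in each silenced library. Its level was 196 ± 10.7 CPM in controls and 9.13 ± 2.32 CPM in silenced cells (SD, n = 3 each), a 21.7-fold reduction with a log2 fold change of -4.44 ± 0.17 (SE) and an edgeR quasi-likelihood adjusted p of 1.22e-05. The raw counts were 3844, 4063 and 3026 in controls and 175, 168 and 151 in silenced libraries. Each of the 4 PSAT1 pseudogenes in the table had at most 12 counts in any library.

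**Figure D2:**
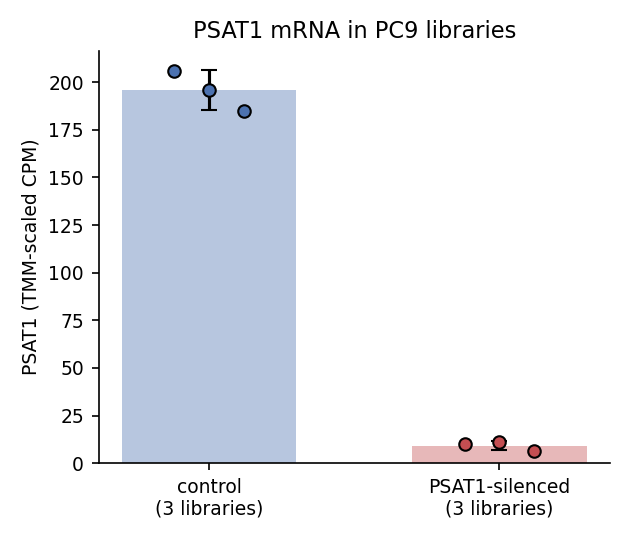
PSAT1 level in TMM-scaled CPM (vertical axis, from 0) for the control and PSAT1-silenced groups, with bars at the mean, whiskers at 1 SD and points for the 3 libraries of each group. Controls lie between 185 and 206 CPM and silenced libraries between 6.53 and 11 CPM.

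With the target included, 2605 of 14515 tested genes passed an adjusted p of 0.05, of which 1373 were higher and 1232 lower in silenced cells. At least 2-fold changes were seen for 494 of them, 204 higher and 290 lower. The groups did not overlap for 38.3% of tested genes, where chance gives 10%. The count was sensitive to single libraries, at 4806 without control replicate 1, 1440 without control replicate 3, and 1110, 1104 and 1188 without silenced replicates 1, 2 and 3. Offsets for GC content and gene length raised it to 5136, while the number changed at least 2-fold stayed between 399 and 623 under these settings. The balance of directions turned with the scaling, at 1184 higher and 1307 lower with RLE size factors, 1194 and 1277 with upper-quartile scaling, 1081 and 1384 with library totals only, and 2485 and 2651 with the offsets. It also turned in DESeq2, with either other count filter, in the test against a fold change of 1.5, and without control replicate 1, 2 or 3 or silenced replicate 1 or 3.

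Among genes with a mean of at least 2 CPM over the 6 libraries, the largest rise was that of A2ML1, a secreted protease inhibitor, 7.41-fold from 0.724 ± 0.167 CPM (SD, n = 3). KRT6B, a keratin of stratified epithelia, rose 6.57-fold, from 8.08 ± 1.26 to 53.03 ± 7.70 CPM (SD, n = 3 each). CHI3L2, a chitinase-like secreted protein, rose 6.22-fold, from 4.09 ± 0.545 to 25.4 ± 0.783 CPM. DNER rose 5.45-fold, FAM129A 4.43-fold, the choline transporter-like gene SLC44A5 3.79-fold, C6orf223 3.47-fold and the transcription factor gene OSR1 3.34-fold. HLA-DQB1, a class II antigen presentation gene, rose 3.91-fold, from 7.17 ± 0.969 to 28.1 ± 0.764 CPM. The chemokine gene CCL20 rose 3.38-fold, and DEPTOR, which encodes an inhibitor of mTOR kinase, rose 3.19-fold, from 15.1 ± 1.40 to 48.1 ± 1.29 CPM. Adjusted p-values of these 11 genes ran from 3.81e-05 for CHI3L2 to 0.0119 for FAM129A. KRT6B and HLA-DQB1 have near-identical relatives or alleles that can take or lose reads. CHI3L2 overlaps DENND2D and C6orf223 overlaps AL109615.3 on the opposite strand, and the strand setting of the counting is not given in the sources used here.

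Of the 10 largest falls other than that of PSAT1 under the same limit of 2 CPM, those of TDRD15 and FGFR2 left at most 1 count over the silenced libraries. TDRD15 had 500 counts over the 3 controls and 0 over the silenced libraries, at least 168-fold lower against a floor of 3 counts over the group. FGFR2, a fibroblast growth factor receptor gene, had 246 counts over the controls and 1 over the silenced libraries, a ratio of 248 with an exact 95% counting interval of 44.1 to 9820. LCP1, which encodes the actin-bundling protein L-plastin, fell 17.8-fold, from 124 ± 8.99 to 6.97 ± 0.497 CPM (SD, n = 3 each), with the smallest adjusted p, 6.61e-07. GSTM1, a glutathione transferase gene, fell 15.4-fold, from 31.4 ± 2.51 to 2.04 ± 0.247 CPM (SD, n = 3 each). The neurotrophin gene BDNF fell 12.6-fold, the corepressor gene TLE4 10.7-fold, KLF12 9.86-fold, EYA4 9.31-fold and FBXO2 6.77-fold, and the serpin gene SERPINB3 had a log2 fold change of -3.47 ± 0.28 (SE). The adjusted p-values of these 10 genes were at most 0.00157, that of FBXO2. GSTM1 overlaps GSTM2 on the same strand, SERPINB3 has a close paralog in SERPINB4, and FBXO2, BDNF and EYA4 overlap FBXO44, BDNF-AS and TARID on the opposite strand, so their counts are uncertain to that extent.

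**Figure D3:**
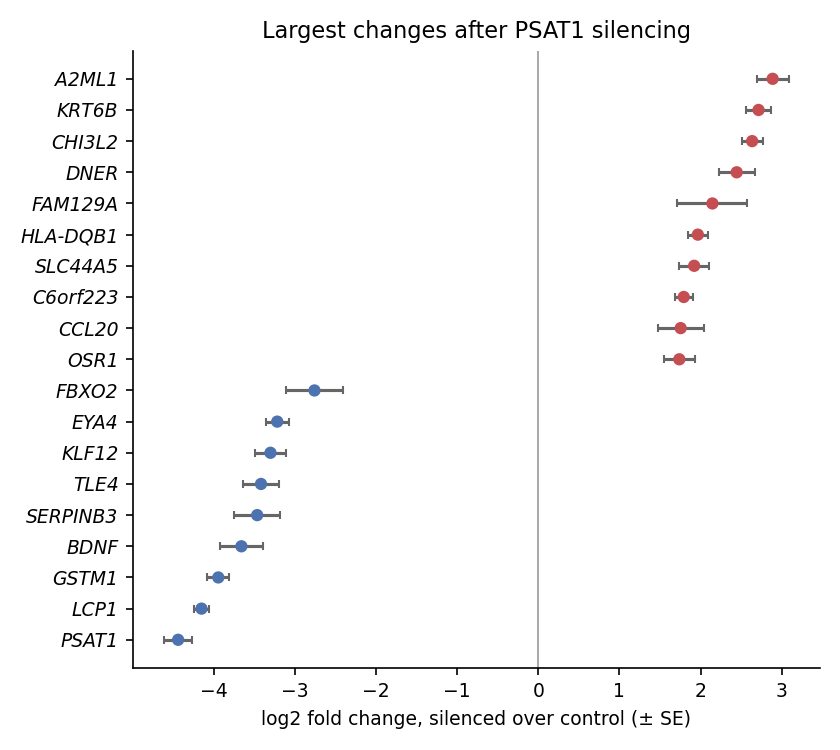
Log2 fold change of silenced over control with its SE (horizontal axis) for PSAT1 and 18 of the 20 other genes with the largest rises (red) or falls (blue) among genes with a mean of at least 2 CPM over the 6 libraries and groups that do not overlap, one gene per row; TDRD15 and FGFR2, with at most 1 count over the silenced libraries, are left out. Values run from -4.44 for PSAT1 to 2.89 for A2ML1.

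Genes of serine synthesis and one-carbon metabolism leaned lower. Of 24 tested members other than PSAT1, 0 rose and 7 fell, and 7 fell when adjusted over the list alone. TYMS, thymidylate synthase, fell 3.50-fold, from 93.95 ± 13.39 to 26.88 ± 2.555 CPM (SD, n = 3 each). ALDH1L1, GLDC and MTHFD1, of folate and glycine metabolism, fell 1.77-, 1.45- and 1.36-fold. ALDH1L1 did not pass without control replicate 3 (adjusted p 0.068) or silenced replicates 1, 2 and 3 (0.0508, 0.0754 and 0.0845), nor GLDC without silenced replicates 1, 2 and 3 (0.109, 0.107 and 0.083). The neighbouring enzymes of the serine pathway did not pass the test, with log2 fold changes of 0.35 ± 0.17 (SE) for PHGDH and -0.07 ± 0.07 for PSPH. The list passed the camera test with an adjusted p of 0.00403, and it did not with an estimated correlation, adjusted p = 0.57. TYMS overlaps TYMSOS and ENOSF1, so its count is uncertain to that extent. It lies in the chromosome 18 block described further on, and the adjusted p of the list was 0.0302 without that block.

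Cell cycle and proliferation genes moved in both directions. Of 52 tested, 6 rose and 17 fell, and 6 rose and 20 fell when adjusted over the list alone. The genes that fell included the G1/S regulators E2F2, CCNE2 and CDC25A, which fell 2.11-, 2.10- and 1.99-fold, and MCM2, MCM3, MCM4 and MCM6 of the replicative helicase. The 6 that rose, MKI67, CENPF, PLK1, BIRC5, CDC20 and KIF20A, are known mainly for mitosis, and their log2 fold changes were 0.29 to 0.55. The camera adjusted p was 0.00563 downward, and the adjusted p with an estimated correlation was 0.762. The list also did not pass without control replicate 1, at 0.0951, or in the fry test, at 0.191.

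Glycolytic and hypoxia-response genes also leaned lower. In the glycolysis and pentose phosphate list 0 of 31 rose and 7 fell, and 1 rose and 10 fell when adjusted over the list alone. The glucose transporter gene SLC2A3 fell 2.02-fold, from 746 ± 51.2 to 369 ± 40.7 CPM (SD, n = 3 each), and the lactate transporter gene SLC16A1, ALDOC and ENO2 had log2 fold changes of -0.60, -0.58 and -0.44 past the threshold. ENO2 did not pass without silenced replicate 2 (adjusted p 0.0579). In the hypoxia list 2 of 25 rose and 10 fell, and 2 rose and 12 fell when adjusted over the list alone. CA12, LOXL2 and ANKRD37 fell 2.21-, 1.85- and 1.68-fold, whereas the secreted hormone gene STC1 rose 1.78-fold. CA12 did not pass without control replicate 3 (0.0922) or silenced replicates 1, 2 and 3 (0.0847, 0.106 and 0.0695), nor ANKRD37 without control replicate 3 (0.0672) or silenced replicates 1 and 2 (0.0729 and 0.0752). The camera adjusted p was 0.00403 for glycolysis and 0.0126 for hypoxia, and with an estimated correlation the adjusted p was 0.601 for each. In the fry test the adjusted p was 0.116 for glycolysis and 0.0738 for hypoxia.

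NF-kB and cytokine genes leaned higher. Of 28 tested, 11 rose and 2 fell, and 15 rose and 2 fell when adjusted over the list alone. TNF rose 2.91-fold, from 0.393 ± 0.125 to 1.17 ± 0.0788 CPM (SD, n = 3 each), and LTB 2.63-fold, beside CCL20. LCN2, NFKBIA, SOD2, IL6 and IL32 were also among those that rose, and LTB did not pass without silenced replicate 1 (adjusted p 0.0506). IL23A fell 2.48-fold and BIRC3 also fell. The camera adjusted p was 0.00403, and the adjusted p with an estimated correlation was 0.601. Of the replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 6 of 9 tested rose and 0 fell, and 7 rose when adjusted over the list alone. HIST2H2BE rose 2.15-fold and HIST1H4H 2.04-fold, and HIST1H2BD and HIST1H2AC had log2 fold changes of 0.90 and 0.86. Their camera adjusted p was 5.67e-05, and the adjusted p with an estimated correlation was 0.57.

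**Figure D4:**
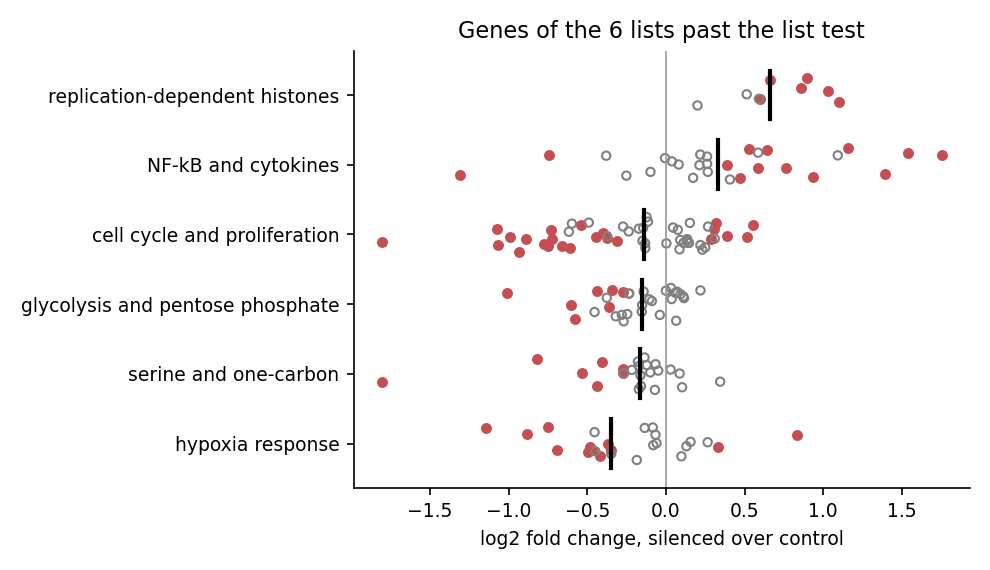
Log2 fold change of silenced over control (horizontal axis) for each tested gene of the 6 lists past the camera test, one list per row, with filled red points for genes at an adjusted p under 0.05, open points for the others and a bar at the median. Medians run from -0.35 for hypoxia to 0.66 for histones.

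The actin cytoskeleton list, fixed because PSAT1 has been studied in cell motility, did not shift as a whole. Of 67 tested, 6 rose and 9 fell, 6 rose and 11 fell when adjusted over the list alone, and the camera adjusted p was 0.546. TAGLN fell 4.23-fold, from 8.08 ± 4.195 to 1.92 ± 0.1075 CPM (SD, n = 3 each), with controls at 4.19, 12.5 and 7.52 CPM. WASF3, an activator of actin nucleation, rose by 1.02 ± 0.15 (SE) on the log2 scale.

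Adhesion, matrix and epithelial lists held changes in both directions and did not pass the camera test. For focal adhesion and integrins 6 of 34 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p 0.278), with ITGB8 up 2.45-fold and PTK2, in a stretch of lower genes on chromosome 8, at a log2 fold change of -0.50. For extracellular matrix and proteases 5 of 36 rose and 10 fell (5 and 10 adjusted over the list alone, 0.144), with TIMP3 3.10-fold down and TNC 3.03-fold up; without control replicate 1 this list passed, at 0.0019. For epithelial junction and identity 10 of 40 rose and 5 fell (12 and 8 adjusted over the list alone, 0.374). For mesenchymal transition 7 of 23 rose and 6 fell (7 and 9 adjusted over the list alone, 0.0847), with FSTL1 4.29-fold and TGFB2 1.98-fold down. For YAP and TGF-beta response 5 of 35 rose and 11 fell (6 and 12 adjusted over the list alone, 0.0724), with ANKRD1 2.98-fold down. This list passed without control replicate 1, at 0.0177, without silenced replicate 2, at 0.0287, and with GC-content and length offsets, at 0.0307.

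Within the EGFR family and ligands, 4 of 16 rose and 4 fell (6 and 4 adjusted over the list alone), and the camera adjusted p was 0.64. The median log2 fold change was 0.15 and the mean -0.21, and the test pointed down. The negative regulator gene LRIG1 fell 13.9-fold, from 1.81 ± 0.454 to 0.1202 ± 0.05918 CPM (SD, n = 3 each), and the ligand genes EGF and TGFA had log2 fold changes of -1.72 and -0.64. ERBB3 rose 1.47-fold. Of the ERK pathway target genes 4 of 34 rose and 4 fell (5 and 8 adjusted over the list alone, camera adjusted p 0.506), with IL11 3.32-fold down and EPHA4 1.80-fold up.

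The amino acid, stress, redox, respiration and lipid lists did not pass the camera test. For ATF4 and amino acid response 1 of 31 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p 0.951). For aminoacyl-tRNA synthetases 1 of 20 rose and 1 fell (1 and 0 adjusted over the list alone, 0.764). For endoplasmic reticulum stress 2 of 24 rose and 1 fell (2 and 1 adjusted over the list alone, 0.546). For p53 target genes 1 of 24 rose and 4 fell (1 and 4 adjusted over the list alone, 0.532). For oxidative phosphorylation 2 of 34 rose and 1 fell (1 and 1 adjusted over the list alone, 0.991). For NRF2 and glutathione 3 of 32 rose and 5 fell (3 and 8 adjusted over the list alone, 0.628), with GSTM3 1.90-fold down and GPX2 at a log2 fold change of 0.67. The median and the direction of the test differed in sign for ATF4 (0.03, down), the synthetases (-0.05, up), NRF2 (0.01, down) and oxidative phosphorylation (-0.01, up). For sterol and fatty acid synthesis 2 of 33 rose and 9 fell (2 and 10 adjusted over the list alone, 0.066). ELOVL6 fell 2.54-fold and FADS2 2.29-fold. The sterol list passed without control replicate 1, at 0.00115, without silenced replicate 2, at 0.0301, and without silenced replicate 3, at 0.032. It also passed with GC-content and length offsets, at 0.0152.

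Interferon-response genes split, with 4 of 35 rising and 9 falling (4 and 9 adjusted over the list alone, camera adjusted p 0.46). OAS2 and CXCL10 rose 4.80- and 4.14-fold from low levels, from 0.346 ± 0.267 to 1.75 ± 0.191 CPM and from 0.559 ± 0.318 to 2.25 ± 0.191 CPM (SD, n = 3 each). IFI44 and USP18 fell 4.04- and 2.19-fold, from 2.315 ± 0.258 to 0.554 ± 0.201 CPM and from 3.47 ± 0.0825 to 1.565 ± 0.297 CPM. For lung epithelial lineage 3 of 11 rose and 1 fell (4 and 2 adjusted over the list alone, 0.278); KRT5, a basal keratin, rose 7.46-fold from 0.202 ± 0.0995 to 1.55 ± 0.375 CPM (SD, n = 3 each), and TP63, a regulator of basal cells, fell 1.69-fold, from 2.43 ± 0.478 to 1.44 ± 0.0524 CPM. TP63 did not pass without control replicate 1 (adjusted p 0.0643) or silenced replicates 1, 2 and 3 (0.0982, 0.123 and 0.0992). Markers of other cells were sparse. For blood and endothelial markers 2 of 7 rose and 0 fell (2 and 0 adjusted over the list alone, 0.299), for fibroblast and smooth muscle markers 1 of 4 rose and 0 fell (1 and 0, adjusted over the list alone, 0.532), and for neuroendocrine and other tumour line markers 0 of 6 rose and 3 fell (2 and 3 adjusted over the list alone, 0.0813).

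Changed genes were also clustered by position, a comparison chosen after the values were seen. Of 52 tested genes on chromosome 18 with starts between 158383 and 14179097 (GRCh38), the short arm, 44 fell and 0 rose, with a median log2 fold change of -0.89, or 1.85-fold lower. The per-library medians relative to the control mean were 0.09, -0.09 and -0.01 in controls and -0.87, -0.87 and -0.85 in silenced libraries. Beyond a stretch without tested genes up to 20946906, 149 genes had a median of -0.06, with 13 rising and 22 falling. The region as the scan drew it ran past that stretch, from 0.2 to 24.2 Mb, with 49 of 69 genes falling and 1 rising. The scan took in every gene of each 31-gene window past the permutation threshold, so region ends are approximate. The myosin light chain genes MYL12A and MYL12B fell 2.53- and 2.29-fold, from 685 and 854 CPM, and VAPA, an endoplasmic reticulum tether gene, fell 2.22-fold. On chromosome 7, genes from 0.0 to 56.1 Mb had a median of 0.39, and 111 of 231 rose and 2 fell. The per-library medians there were -0.04 to 0.03 in controls and 0.40 to 0.41 in silenced libraries. That stretch holds EGFR, which rose 1.43-fold, from 832 ± 76.85 to 1191 ± 7.39 CPM (SD, n = 3 each, adjusted p 0.00304), and also ITGB8, IL6 and PSPH. Changes of named genes on the short arm of chromosome 18 and in this stretch were not separated from the shift of their neighbours.

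**Figure D5:**
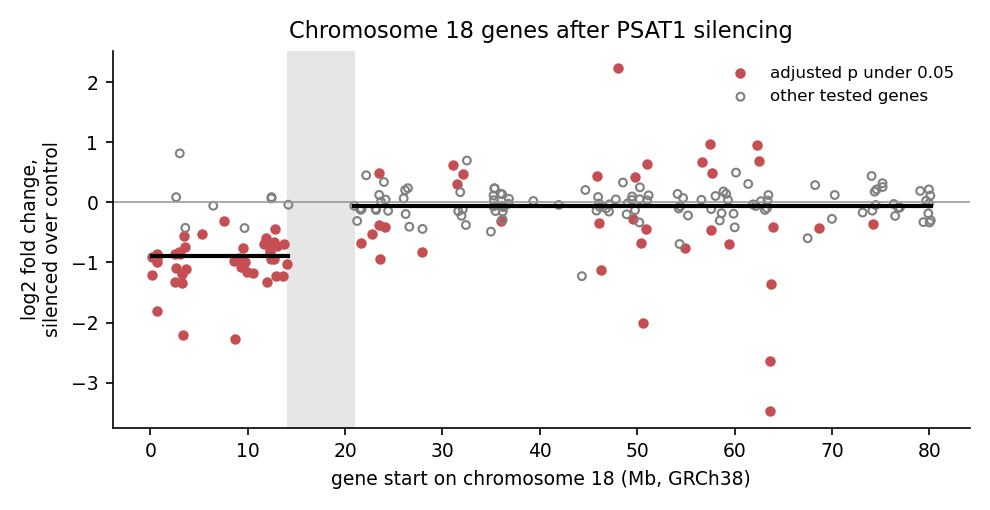
Log2 fold change of silenced over control (vertical axis) against gene start on chromosome 18 in Mb (horizontal axis, GRCh38), with filled points for genes at an adjusted p under 0.05, open points for other tested genes, bars at the medians and grey for the stretch without tested genes. The median is -0.89 before that stretch and -0.06 after it.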

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

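The alternatives that leave out genes by position were chosen after the data were seen. PSAT1 stayed lower and past the threshold in each alternative, with log2 fold changes of -4.59 to -4.29. Of 420 values of 21 other genes with the largest changes or smallest p, 419 kept direction and threshold and 1, FAM129A at an adjusted p under 0.01, did not pass; none reversed. Of 2186 values of 110 named genes, 163 kept the direction and did not pass, and 74 genes passed throughout. Other size factors, count filters, DESeq2, limma-voom and the robust fit gave 2236 to 3175 changed genes, and among these the share called higher ran from 43.9% with library totals only to 54.4% with limma-voom, against 52.7%. A stricter adjusted p of 0.01 gave 1022 genes, 529 higher and 493 lower, and a test against a fold change of 1.5 gave 288, 110 higher and 178 lower, 259 of them at least 2-fold; both are stricter by construction. Leaving out 1 library gave 1104 to 4806 genes, 438 to 2275 higher and 535 to 2531 lower, 399 to 623 at least 2-fold, the highest without control replicate 1 and the lowest without silenced replicate 2 for the total. Offsets for GC content and length gave 5136 genes, 2485 higher and 2651 lower, with 98.8% of the 2605 genes called without offsets kept. The same replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.156, 0.02 and -0.042, and of the 6 libraries 1, silenced replicate 2, correlated best with its own number. With the replicate block the count was 1473, 759 higher and 714 lower, and with the block and the offsets it was 4811, 2342 higher and 2469 lower.

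Between 5 and 8 lists passed under the alternatives, except 0 with an estimated correlation. That setting estimated the inter-gene correlation of each list in place of the fixed 0.01. The estimates were 0.035 to 0.283 for the 6 lists that passed the main test, above the value it assumed. The camera p also rose for lists with estimates below 0.01. For the mesenchymal list, at -0.026, the unadjusted p went from 0.0326 to 0.0776. For the neuroendocrine list, at -0.031, it went from 0.0281 to 0.0877. Higher correlation is therefore not the whole reason that 0 lists passed. Why members of the 6 lists varied together was not tested. The actin list passed under none of 19 alternatives, with adjusted p from 0.0951 to 0.811. Without the genes of 16 shifted regions 2098 genes were called, and 8 lists passed, the 6 of the report among them. Leaving out the chromosome 18 short-arm genes gave 2537 genes. In the fry test 5 lists passed. Of the 6 lists past the main test, these were serine and one-carbon (adjusted p 0.0145), NF-kB (0.0255) and histones (0.00642), and the cell cycle, glycolysis and hypoxia lists did not pass. The mesenchymal and neuroendocrine lists also passed, at 0.00265 and 0.0145. The sterol list passed in 8 and the YAP list in 6 of 19 alternatives. Both passed the camera test with the GC-content and length offsets, at adjusted p 0.0152 and 0.0307. With the offsets and the replicate block both were at 0.0124. Scaling without mitochondrially encoded genes was not run because the table holds none. At this depth the simulations, with 200 changed genes and no GC-content trend, recovered 80.4% of 2-fold changes. Smaller changes are less completely counted, and recovery under the GC-content trends of these controls was not simulated.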

Other observations

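Tests of the chromosome 18 scaling and step, and of the PSAT1 level in control replicate 1, were chosen after their results were seen. Regions of shifted expression were found on several chromosomes. The scan gave 16 regions with 1107 tested genes. In 12 regions each silenced library lay outside the range of the controls, and in 4 the ranges overlapped, among them chromosome 8 from 126.6 to 145.1 Mb. The scan picked the regions from the fold changes of these same libraries, so that separation is partly built in. On chromosome 5, genes from 0.2 to 41.9 Mb had a median log2 fold change of 0.32, with 41 of 102 rising and 6 falling. On chromosome 7, beyond the higher stretch that ends at 56.1 Mb, genes from 65.0 to 76.0 Mb had a median of -0.32, with 1 of 61 rising and 18 falling. On chromosome 17, genes from 5 to 12 Mb had a median of -0.31, with 0 of 96 rising and 25 falling.

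The fall of short-arm genes on chromosome 18 was not removed by offsets for GC content and gene length, after which the median was -0.93. The short-arm median minus that beyond the gap was -0.83, which argues against scaling of the libraries, since scaling would move both alike. Chance clustering is argued against by the permutation p of 0.001, the smallest that 1000 permutations can give. A difference in chromosome 18 copy number between the control and silenced populations stays open. The median stepped up by 0.65, from -0.76 over the 20 tested genes before the gap to -0.11 over the 20 after it. That step followed from medians already seen, and expression does not tell a loss in one population from a gain in the other. The scanned region ran past the gap to 24.2 Mb. A region took in every gene of each 31-gene window past the permutation threshold, so its end cannot place the edge of the shift. DNA was not analysed here and a copy-number difference was not tested for chromosome 7, and whether the falls of TYMS, MYL12A, MYL12B and VAPA, and the rises of EGFR, ITGB8 and IL6 in the higher stretch of chromosome 7, follow PSAT1 depletion or a difference that arose in either population stays open.

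Replication genes were lower while mitotic genes were not. In G1/S and G2/M lists without members of the fixed list, 16 of 36 G1/S genes fell and 0 rose, with a median log2 fold change of -0.46. Of 39 G2/M genes 8 rose and 1, NDC80 on the chromosome 18 short arm, fell, with a median of 0.16. No member of either list was left out for lying in a shifted region. The G1/S median stayed at -0.47 after the GC-content and length offsets, which argues against such a trend as the whole cause. The G1/S minus G2/M difference was -0.62 (permutation p over genes 1e-05, the smallest that 100000 permutations can give; genes are not independent replicates), and a candidate explanation is a smaller share of cells entering S phase, with lower transcription of these genes at the same share left open. The replication-dependent histone genes ran the other way, with 6 of 9 rising and a median of 0.66. Their transcripts mostly lack a poly(A) tail and the libraries were poly(A)-enriched, so most of their S-phase transcripts may be uncounted. Their rise therefore cannot decide for or against that explanation.

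Control replicate 1 stood apart from the other controls. Offsets for GC content and length removed 59.8% of its mean squared log2 deviation from the mean of the other controls, from 0.205 to 0.0824. The offsets corrected every library, and control replicate 2 leaned the opposite way in GC content. GC-content and length trends of the controls together may account for most of that distance. The part due to control replicate 1 alone was not measured. Its PSAT1 level of 206 CPM argues against a mislabelled silenced library. No biological explanation was tested for this library.

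Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 2605 genes in edgeR's quasi-likelihood test, and the highest of the others gave 0; 10 splits are too few for a share under 0.05.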
